A study of Mus musculus with 6 samples.

How the data were processed

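Single-cell RNA libraries of mouse tumours were analysed, 3 from tumours injected with PBS and 3 from tumours injected with PTEN. Per the file headers, the authors made each deposited matrix of whole UMI counts per gene and barcode with Cell Ranger 7.0.0, whereas the submitters' processing notes name Cell Ranger 2.1.1 and the genome build mm39. The conflict over the version could not be settled from the files. Barcodes had already been filtered to called cells before deposit, and each matrix held 1 library. The files pair 32285 gene identifiers with symbols, which are used as given. No coordinates are printed, because the reference at hand is of another build. Per the labels' protocols, red cells were lysed and dead cells were removed with magnetic beads before loading, and 8000 cells were targeted per library, against 5856 to 7386 barcodes in the files.

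Everything that follows was computed from those counts. A barcode was kept with at least 200 detected genes and at most 20% mitochondrial UMIs. Doublets were scored against simulated pairs of cells by the method of Scrublet, written anew, with an expected rate of 0.8% per 1000 barcodes, and 1653 barcodes were removed. The threshold came from the minimum of the simulated scores in PBS replicate 2 and PTEN replicate 3, and from the expected rate in the other libraries, where no usable minimum was found. Of 39338 barcodes, 34318 cells stayed. Counts were scaled per cell and log transformed, 2000 variable genes gave 30 principal components, and a graph over 20 nearest neighbours was partitioned with leidenalg 0.10.2 at resolution 1. Clusters were named from marker lists fixed before the data were examined, with at least 3 detected markers, a marker score of at least 0.4 and a ratio of at least 1.5 to the next class. These minimums were set after the clusters and their libraries were seen. A cluster also stayed unnamed where markers of another class led it, or where it was shallow and led by none of its own markers. Lymphoid cells were clustered again. Clusters without a name held 5.67% ± 0.984 (SD, n = 3) of kept cells in the PBS libraries and 3.07% ± 0.925 (SD, n = 3) in the PTEN libraries. No monocyte-like cluster stood apart at resolution 1, so the monocyte/macrophage-like class held macrophage-like clusters; at resolution 2 a monocyte-like cluster was split off.

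Counts were summed per library and class, and a class of the original plan was tested only where every library held at least 20 of its cells. Pericyte or smooth muscle-like, B cell-like and red blood cell-like cells were planned for shares alone. Sums were compared with the quasi-likelihood test of edgeR 4.0.16 with TMM scaling and its own filter on low counts, and p-values were adjusted by Benjamini and Hochberg at 0.05 over the genes of a class. CPM are counts per 1e6 of the TMM-scaled library size. Gene lists fixed before the data were examined were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over all 76 tests of a list in a class, for lists with at least 5 measured genes. The lists of haemoglobin transcripts and of sex-linked genes fell below that number and were not tested. Shares of cells were compared with a two-sided exact permutation test over 20 arrangements, whose smallest p is 0.1. A fold against a group with no count is a lower bound from a floor of 3 counts over the group. Where a group held 1 to 3 counts, the ratio has an exact interval of 95% that covers counting error alone.

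Most genes named in the text followed a rule fixed before the data were examined. It took Pten, Plxdc2 and Plxdc1, the genes of largest change whose 3 PTEN libraries all lay to the same side of the 3 PBS libraries, and for each list the 2 members with the smallest adjusted p, or the member of highest mean where none passed. Predicted genes and variable segments of antigen receptors were left out. Genes said to lead or mark a cluster were named outside this rule. So were Malat1, Gm42418, Lars2, Camk1d, Cmss1 and Gphn in endothelial cell-like cells, and genes of the untested NK cell-like and dendritic cell-like classes, Plxdc2 apart.

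The count test was tested on simulated data drawn from the real means, spreads and library sizes, with 200 changed genes. At a change of 4-fold it recovered between 97% of the genes, in whole libraries, and 100%, in the monocyte/macrophage-like class among others. At 2-fold it recovered 90% in the monocyte/macrophage-like class, 95% in the melanoma-like class, 66% in the T cell-like class, 64% in the neutrophil-like class, 85% in the endothelial cell-like class, 59% in the fibroblast-like class and 70% in whole libraries. False calls were between 4.05% and 7.74% of calls. The changed genes were not drawn from those of lowest mean, and the counts followed the negative binomial model that edgeR fits. Recovery of scarce transcripts and false calls in real data were therefore not measured.

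Alternatives planned before the data were examined were DESeq2 1.42.0, limma with voom weights, RLE scaling, weaker and stricter filters on counts and cells, other cluster resolutions, doublets kept, equal cell numbers per library, the replicate number as a block, and each library left out. Macrophage-like clusters alone were taken at resolution 2, so that setting changed resolution and class together. Endothelial cell-like cells of at least 5000 UMIs, and genes under 10% of their CPM in another class, either pooled over both groups or in the same group, were added after the data were seen. Percentages of a level in another class set counts summed over the group in which the gene was higher against the other class in that group. Of the list symbols, 6 are absent from the files. Total counts per library ranged from 152506079 to 179122742 UMIs. Whole-library sums of every pair of libraries differed beyond sampling noise, with a chi-square per degree of freedom of at least 36.4, so no library repeated another. Cells and classes differ between libraries in any case, so this does not show biological replication. Each library was counted as 1 replicate. The labels do not say whether libraries came from separate animals, so p-values measure the spread between these samples, which may be technical. No batch is named in the labels.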

Results

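B16-F10 is a pigmented mouse melanoma line, and a PTEN knockout version of it was grown under the skin of C57BL/6J mice. PTEN is a phosphatase that opposes PI3K signalling. Tumours of about 100 mm3 received either PTEN at 10 µg per day or PBS for 7 days, injected into the tumour. Dissociated tumour cells were then profiled with droplet-based 3′ single-cell RNA sequencing in 3 libraries per group. The PBS libraries held 167247125, 166039592 and 152506079 UMIs in replicates 1, 2 and 3. The PTEN libraries held 179122742, 178407283 and 162965572 UMIs. After filtering, 34318 cells fell into 11 named classes. The design asks how the cells of a PTEN-deficient tumour differ after PTEN has been supplied from outside. Plxdc2 and Plxdc1, which encode transmembrane proteins of the plexin domain family, were followed beside Pten because Plxdc2 has been described as a receptor for secreted PTEN.

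Pten transcripts (ENSMUSG00000013663) were present in melanoma-like cells of every library, at 109.8, 117.2 and 116.5 CPM with PBS and 101.5, 100.0 and 108.4 CPM with PTEN. Their log2 difference, PTEN minus PBS, was -0.15 ± 0.05 (SE, n = 3 per group; edgeR adjusted p = 0.165). A 3′ tag does not report a frameshift or deletion elsewhere in the gene, so these values do not test the knockout. In monocyte/macrophage-like cells the log2 difference of Pten was -0.07 ± 0.14 (SE, n = 3 per group; edgeR adjusted p = 0.815), and in T cell-like cells it was 0.29 ± 0.26 (SE, n = 3 per group; edgeR adjusted p = 0.725). In whole libraries it was -0.14 ± 0.05 (SE, n = 3 per group; edgeR adjusted p = 0.183).

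Conventional dendritic cell-like cells made up 1.90% ± 0.319 (SD, n = 3) of kept cells in the PBS libraries and 0.301% ± 0.0870 (SD, n = 3) in the PTEN libraries. B cell-like cells made up 1.32% ± 0.474 and 0.247% ± 0.191 (SD, n = 3 each), and fibroblast-like cells 2.82% ± 0.209 and 1.64% ± 0.507 (SD, n = 3 each). Pericyte or smooth muscle-like cells were at 0.768% ± 0.224 with PBS and 0.487% ± 0.0486 with PTEN (SD, n = 3 each). NK cell-like cells went the other way, with 0.183% ± 0.0593 in the PBS and 0.304% ± 0.0668 in the PTEN libraries (SD, n = 3 each). As shares of all kept cells these 5 classes did not overlap between the groups, and each gave an exact permutation p of 0.1, the smallest this design allows, with an adjusted p of 0.220. As shares of cells outside the melanoma-like class, dendritic cell-like, B cell-like and NK cell-like cells still gave an exact permutation p of 0.1. Fibroblast-like cells, at 7.98% ± 2.70 and 5.84% ± 1.22, and pericyte or smooth muscle-like cells, at 2.31% ± 1.38 and 1.80% ± 0.434 (SD, n = 3 each), then overlapped between the groups (exact permutation p = 0.3 and 0.8). None of the 11 shares could pass 0.05 in this test, whereas edgeR on cell counts called the dendritic cell-like class (log2 ratio -2.64, adjusted p = 0.00119). Melanoma-like cells held 61.3% ± 15 and 72.0% ± 7.10 of kept cells, and monocyte/macrophage-like cells 16.7% ± 7.18 and 10.1% ± 1.96 (SD, n = 3 each), with overlapping libraries. T cell-like cells were at 1.39% ± 0.271 and 1.45% ± 0.361, and endothelial cell-like cells at 0.995% ± 0.0811 and 0.872% ± 0.0825 (SD, n = 3 each). Neutrophil-like cells held 6.72% ± 8.54 and 9.38% ± 4.63 (SD, n = 3 each). The log2 ratio of their mean shares, 0.48, became 2.38 without PBS replicate 2, which held 16.6% neutrophil-like cells, and -0.01 without PBS replicate 1. Red blood cell-like cells were at 0.245% ± 0.314 and 0.230% ± 0.150 (SD, n = 3 each), after lysis of red cells in the protocol. Their log2 ratio of -0.09 became 1.86 without PBS replicate 2. Outside the melanoma-like class the log2 ratio of neutrophil-like cells was 1.22, and those of endothelial cell-like and red blood cell-like cells turned to 0.19 and 0.63 (exact permutation p = 0.2, 0.7 and 0.5). H2-Eb1, Mgl2 and Ccl22, which mark the dendritic cell-like cluster or class, also differed between the groups within other cells, so this share is not independent of expression.

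**Figure D1:**
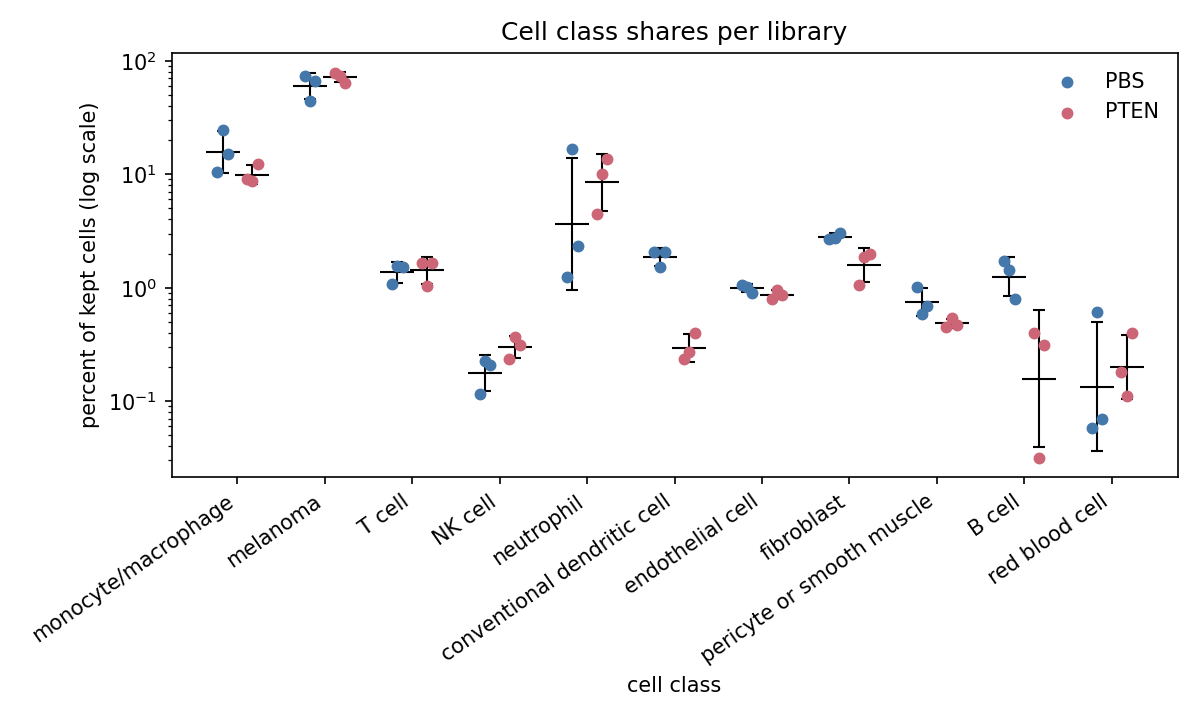
Percent of kept cells in each named class, on a log axis, for each library (points, PBS in blue and PTEN in red); black bars mark the geometric mean and its SD on the log scale, n = 3 per group. Conventional dendritic cell-like cells lay between 1.53% and 2.08% in the PBS libraries and between 0.234% and 0.4% in the PTEN libraries.

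Monocyte/macrophage-like cells of the PTEN libraries carried far more Saa3 (ENSMUSG00000040026), an acute-phase serum amyloid, at 17240 ± 3141 CPM against 49.2 ± 20.2 CPM with PBS (SD, n = 3 each), a log2 change of 8.42 ± 0.30 (SE; edgeR adjusted p = 2.06e-08). Marco, a scavenger receptor for bacteria and particles, rose by 4.35 ± 0.33 on the log2 scale (SE; edgeR adjusted p = 8.51e-06), and Fpr1, the receptor for formylated peptides, rose by 4.03 ± 0.21 (SE; edgeR adjusted p = 7e-07). Saa1, a related serum amyloid with no count in the PBS libraries, was at least 41.7-fold higher. Retnla (ENSMUSG00000061100), a secreted product of alternatively activated macrophages, had 1297 counts with PBS and none with PTEN, at least 246-fold lower. The eosinophil-attracting chemokine Ccl24 fell by 7.95 ± 0.48 on the log2 scale (SE; edgeR adjusted p = 1.44e-06), and the haemoglobin scavenger receptor Cd163 fell by 4.29 ± 0.66 (SE; edgeR adjusted p = 0.00131). Ifnb1, which encodes interferon beta, had 74 counts with PBS and none with PTEN, at least 14.0-fold lower. The lectin Mgl2 and the ribonuclease Rnase2a each had 1 count with PTEN, a 268-fold (interval 47.8 to 10590) and a 124-fold (interval 21.99 to 4912) lower ratio. Lcn2, a siderophore-binding protein, rose by 4.64 ± 0.51 and Csf3, the granulocyte growth factor, by 4.14 ± 0.55 on the log2 scale (SE). Free RNA can add to some of these values: within the PTEN libraries Lcn2 stood at 2.70% of its level in neutrophil-like cells, Csf3 at 7.47% and Fpr1 at 9.46%, and within the PBS libraries Mgl2 stood at 6.76% of its level in dendritic cell-like cells.

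Plxdc2 (ENSMUSG00000026748) fell in the same class from 35.6 ± 3.07 to 18.6 ± 4.42 CPM (SD, n = 3 each), by 0.96 ± 0.18 on the log2 scale (SE; edgeR adjusted p = 0.00545). In the PBS libraries it stood at 7.31% of its level in pericyte or smooth muscle-like cells, so a part from free RNA stays open. Its 35.6 CPM lay above the 19.5 ± 2.67 CPM (SD, n = 3) of all kept cells with PBS. Free RNA with the make-up of all kept cells could thus not be its only source. Plxdc1 stood at 26.1 ± 3.12 and 21.3 ± 3.17 CPM (SD, n = 3 each; edgeR adjusted p = 0.339).

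Of 19 measured alternatively activated macrophage genes, 8 fell, among them the mannose receptor Mrc1 (ENSMUSG00000026712; log2 -1.70 ± 0.11, SE) and Ccl24, 2 rose and 9 did not pass; 8 fell and 4 rose adjusted over the list alone. MHC class II presentation fell in 7 of 9 measured genes, with none rising, and 7 fell adjusted over the list alone; H2-Eb1, a chain of the antigen-presenting complex, changed by -1.36 ± 0.15 and its peptide loader H2-DMb1 by -1.34 ± 0.15 on the log2 scale (SE). Among 38 interferon response genes 14 fell, 1 rose and 23 did not pass (23 fell and 1 rose adjusted over the list alone); Ifit2 changed by -1.43 ± 0.23 and the guanylate-binding protein Gbp3 by -1.18 ± 0.18 (SE). Of 18 NF-kB feedback genes 8 rose, none fell and 10 did not pass (12 rose adjusted over the list alone). The mitochondrial superoxide dismutase Sod2, at 1.79 ± 0.16, and the NF-kB inhibitor Tnip1, at 1.15 ± 0.15 (SE), were among those that rose. Of 17 chemokines 7 fell and 2 rose (8 fell and 2 rose adjusted over the list alone), with the monocyte attractant Ccl12 at -2.56 ± 0.20 (SE). Inflammatory macrophage genes split: the T cell attractant Ccl5 rose by 3.37 ± 0.27, the arginine transporter Slc7a2 and 1 other gene fell, and 13 of 16 did not pass (2 rose and 3 fell adjusted over the list alone); Slc7a2 changed by -1.76 ± 0.29 (SE). Of 18 phagocytosis receptors 6 fell, 2 rose and 10 did not pass (6 fell and 3 rose adjusted over the list alone), Mrc1 and Marco being the members of smallest p. In MHC class I presentation 2 of 20 genes rose and 2 fell (2 and 3 adjusted over the list alone), with H2-Q7 at 0.79 ± 0.19 and H2-K1 at 0.49 ± 0.12 (SE). Hypoxia response had 2 of 23 genes falling and none rising (3 adjusted over the list alone), Bhlhe40 at -0.75 ± 0.17 and Ankrd37 at -0.91 ± 0.22 (SE). Cell cycle genes had 2 of 35 falling and none rising (2 adjusted over the list alone), the replication clamp Pcna at -0.65 ± 0.11 and the centromeric histone Cenpa at -0.71 ± 0.18 (SE). None of 26 sterol and fatty acid synthesis genes passed in edgeR, nor adjusted over the list alone; Ldlr, the low-density lipoprotein receptor, was at 0.29 ± 0.11 (SE; adjusted p = 0.134).

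With camera at the preset correlation, the alternatively activated (adjusted p = 0.00932), interferon response (2.40e-07), MHC class II (6.70e-09), chemokine (0.000589), hypoxia response (0.00269) and cell cycle (0.00219) lists were lower and NF-kB feedback genes higher (1.78e-07) in these macrophage-like cells. None kept its call with an estimated correlation, at adjusted p = 0.480 for the alternatively activated, MHC class II, chemokine and NF-kB lists, 0.498 for interferon response, 0.571 for hypoxia response and 0.638 for cell cycle. Inflammatory macrophage genes (adjusted p = 1.00), MHC class I (0.983), phagocytosis receptors (0.130) and sterol synthesis (0.151) did not pass camera. The median of the inflammatory list was -0.07 and its mean 0.05, with a test directed lower. The phagocytosis receptors had a median of 0.02, a mean of -0.23 and a test directed lower. Mitochondrially encoded RNA (median log2 0.15, adjusted p = 0.0275) and free melanoma RNA (median log2 0.39, adjusted p = 0.0127) were higher in the same cells, with adjusted p = 0.638 and 0.571 with an estimated correlation. Stress genes of dissociation did not pass (median log2 -0.21, adjusted p = 0.210).

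In all, 1079 of 10741 genes changed in monocyte/macrophage-like cells by the edgeR test, 470 higher and 609 lower with PTEN. The libraries of the groups did not overlap for 29.1% of tested genes, where chance gives 10%. The PBS cells lay mostly in a cluster led by Arg1, Ccl6 and Pf4, the PTEN cells mostly in a cluster led by Saa3, Lyz2 and Ms4a7. Replacement of cells and a change of transcripts within cells are thus not separated by the sums. The count was 713 without PTEN replicate 1, 624 without PTEN replicate 2 and 711 without PTEN replicate 3. Among 29 named genes that passed, leaving out a library ended the call of H2-K1 without PBS replicate 1 (adjusted p = 0.0788), of 3 genes without PBS replicate 3 (Bhlhe40, Ankrd37, Cenpa; 0.0505 to 0.0867), of 5 without PTEN replicate 1 (those 3, H2-Q7 and H2-K1; 0.0696 to 0.112), of 4 without PTEN replicate 2 (Rnase2a, H2-K1, Bhlhe40, Ankrd37; 0.0528 to 0.107) and of 3 without PTEN replicate 3 (H2-Q7, Rnase2a, Cenpa; 0.0534 to 0.107). DESeq2 ended the call of Cenpa (adjusted p = 0.0631) and limma with voom weights that of Rnase2a (0.0555).

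**Figure D2:**
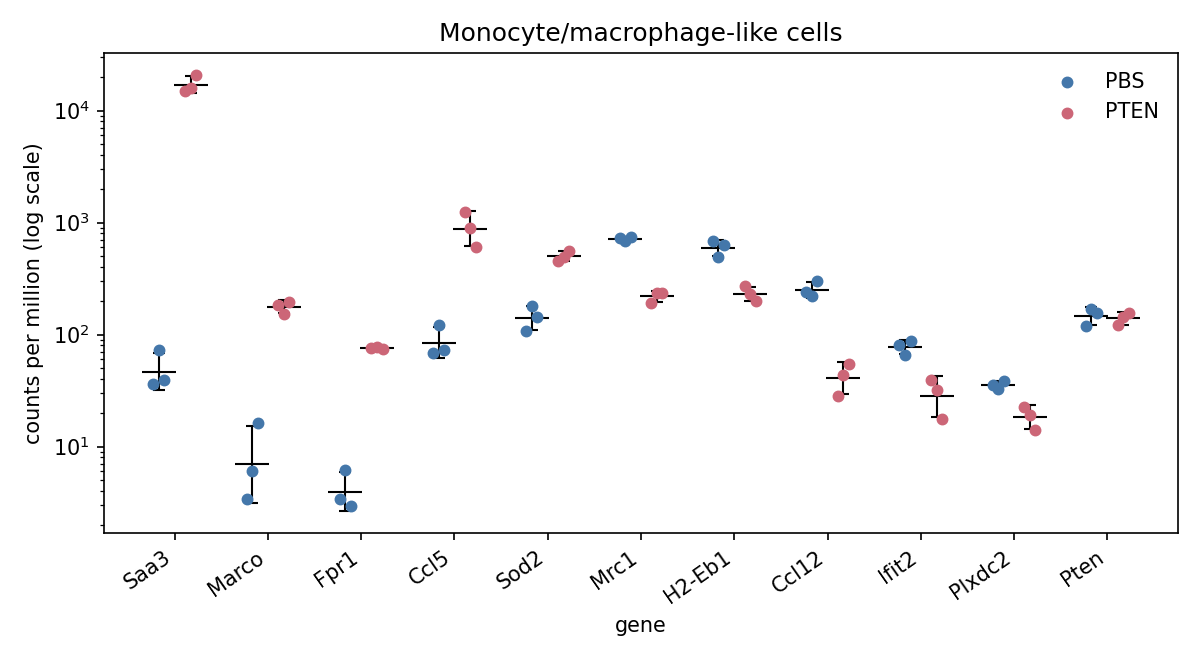
CPM of 11 named genes in monocyte/macrophage-like cells, on a log axis, for each library (points, PBS in blue and PTEN in red); black bars mark the geometric mean and its SD on the log scale, n = 3 per group. Saa3 lay between 36.0 and 72.5 CPM with PBS and between 15040 and 20830 CPM with PTEN, while Pten overlapped between the groups.

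Melanoma-like cells of the PTEN libraries had lower transcripts of the hypoxia response, of which 15 of 24 measured genes fell, none rose and 9 did not pass (19 fell adjusted over the list alone). The carbonic anhydrase Car9 (ENSMUSG00000028463) fell from 76.3 ± 2.60 to 44.1 ± 5.46 CPM (SD, n = 3 each), by 0.79 ± 0.08 on the log2 scale (SE; edgeR adjusted p = 0.00375), and Ankrd37 by 0.85 ± 0.10 (SE; edgeR adjusted p = 0.00564). The 2 melanoma-like clusters led by both Ankrd37 and Car9 held fewer cells in each PTEN library than in any PBS library. Another cluster, led by Car9 without Ankrd37, overlapped between the groups, with 511, 302 and 415 cells with PBS and 327, 582 and 444 with PTEN. Since these genes define such clusters, fewer cells of this kind and fewer transcripts per cell are not separated by the sums. Glycolysis fell in 3 of 20 genes with none rising (8 adjusted over the list alone), including the glucose transporter Slc2a1 at -0.63 ± 0.09 and phosphofructokinase Pfkp at -0.34 ± 0.06 (SE). FOXO targets fell in 3 of 25 genes with none rising (7 adjusted over the list alone), the cyclin-dependent kinase inhibitor Cdkn1b at -0.37 ± 0.06 and Ccng2 at -0.63 ± 0.12 (SE). Of 15 neural crest or dedifferentiated melanoma genes 3 fell and none rose (4 adjusted over the list alone), fibronectin Fn1 at -0.70 ± 0.08 and the collagen cross-linker Loxl2 at -0.38 ± 0.07 (SE). Fn1 stood at 0.967% of its level in fibroblast-like cells with PBS, which leaves free RNA open. In melanocyte differentiation 1 of 20 genes rose and none fell (4 rose and 2 fell adjusted over the list alone), the lineage factor Sox10 at 0.34 ± 0.07 (SE). Among 22 p53 and apoptosis genes only Chac1, which degrades glutathione, rose, by 1.12 ± 0.23 (SE), the 1 gene adjusted over the list alone as well.

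No gene of the interferon response (38 measured), MHC class I presentation (20), sterol and fatty acid synthesis (28) or the cell cycle (36) passed the edgeR test in these cells. Adjusted over the list alone, 7 interferon genes fell, 1 MHC class I gene fell, 1 sterol gene rose and 1 fell, and 6 cell cycle genes rose. Values of their most expressed members were -0.08 ± 0.11 for the membrane tether Bst2, 0.34 ± 0.17 for B2m, 0.15 ± 0.07 for Fdps and 0.19 ± 0.06 for the topoisomerase Top2a (log2, SE, n = 3 per group). By camera at the preset correlation, hypoxia response (adjusted p = 3.12e-18), glycolysis (1.78e-07), interferon response (4.46e-07), FOXO targets (0.00286) and neural crest genes (0.0107) were lower and cell cycle genes (0.000417) higher. None passed with an estimated correlation: the adjusted p was 0.480 for hypoxia response and glycolysis, 0.565 for interferon response, FOXO targets and neural crest genes, and 0.648 for the cell cycle. The melanoma-like cluster led by Iigp1, Igtp and Ifit3 held 217, 164 and 531 cells with PBS and 148, 190 and 134 with PTEN. Its PBS cells thus lay mostly in PBS replicate 3. MHC class I (0.247), sterol synthesis (0.205), p53 targets (0.983) and melanocyte differentiation (0.473) did not pass camera. The p53 targets had a median of -0.02, a mean of 0.02 and a test directed lower. Mitochondrially encoded RNA was higher beside these lists (median log2 0.19, adjusted p = 0.00272; adjusted p = 0.565 with an estimated correlation). The free melanoma RNA list, which in this class holds the cells' own transcripts (median log2 0.12, camera adjusted p = 0.157), and stress genes (median log2 -0.11, adjusted p = 0.115) did not pass.

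The largest changes in melanoma-like cells were of transcripts that belong to myeloid or B cells. Saa3 rose by 3.92 ± 0.20 on the log2 scale (SE; edgeR adjusted p = 6.23e-05) to 45.0 ± 9.04 CPM (SD, n = 3), which is 0.257% of its level in monocyte/macrophage-like cells of the same libraries. Lcn2, Wfdc21, Csf3 and Ly6i also rose, by 4.76 ± 0.66, 5.08 ± 0.65, 3.63 ± 0.61 and 3.35 ± 0.54 (SE), and each stood under 1% of its level in neutrophil-like cells of the same libraries. Ighg3, an antibody constant region, was at least 235-fold higher. Retnla was at least 89.4-fold lower, and Clec10a and Ear2 changed by -3.85 ± 0.68 and -3.84 ± 0.67 (SE). With 1 to 2 counts left in the PTEN libraries, Ccl24 was 417-fold (interval 74.5 to 16530), Mgl2 137-fold (interval 24.1 to 5451) and Ccl22 53.7-fold (interval 14.5 to 449.4) lower. Of the 365 changed genes, 101 had a CPM under 10% of that in another class of the same group. Plxdc2 stood at 14.2 ± 2.93 and 13.7 ± 1.71 CPM and Plxdc1 at 4.796 ± 0.469 and 5.67 ± 0.959 CPM (SD, n = 3 each), neither passing (edgeR adjusted p = 0.891 and 0.332).

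By the edgeR test 365 of 17851 genes changed in melanoma-like cells, 117 higher and 248 lower with PTEN, and the libraries did not overlap for 24.9% of genes, where chance gives 10%. DESeq2 called 1316 and edgeR without a low-count filter 588. The edgeR count was 159, 153 and 149 without PBS replicates 1, 2 and 3, and 128, 35 and 952 without PTEN replicates 1, 2 and 3. Of 22 named genes that passed, 14 lost the call without PTEN replicate 2 (adjusted p from 0.0609 to 0.185), among them Wfdc21, Lcn2, Slc2a1 and Cdkn1b. Between 6 and 9 lost it without PTEN replicate 1 (9 genes, 0.0638 to 0.121) or PBS replicate 1 (8 genes, 0.0560 to 0.0746), 2 (6 genes, 0.0561 to 0.0969) or 3 (7 genes, 0.0560 to 0.115), Chac1, Sox10 and Pfkp in each of these. Chac1 also lost its call with equal cell numbers (adjusted p = 0.0520), and Clec10a and Chac1 lost theirs with voom weights (0.0502 and 0.0607). Car9, Ankrd37, Fn1, Saa3 and Retnla were called under every left-out library.

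**Figure D3:**
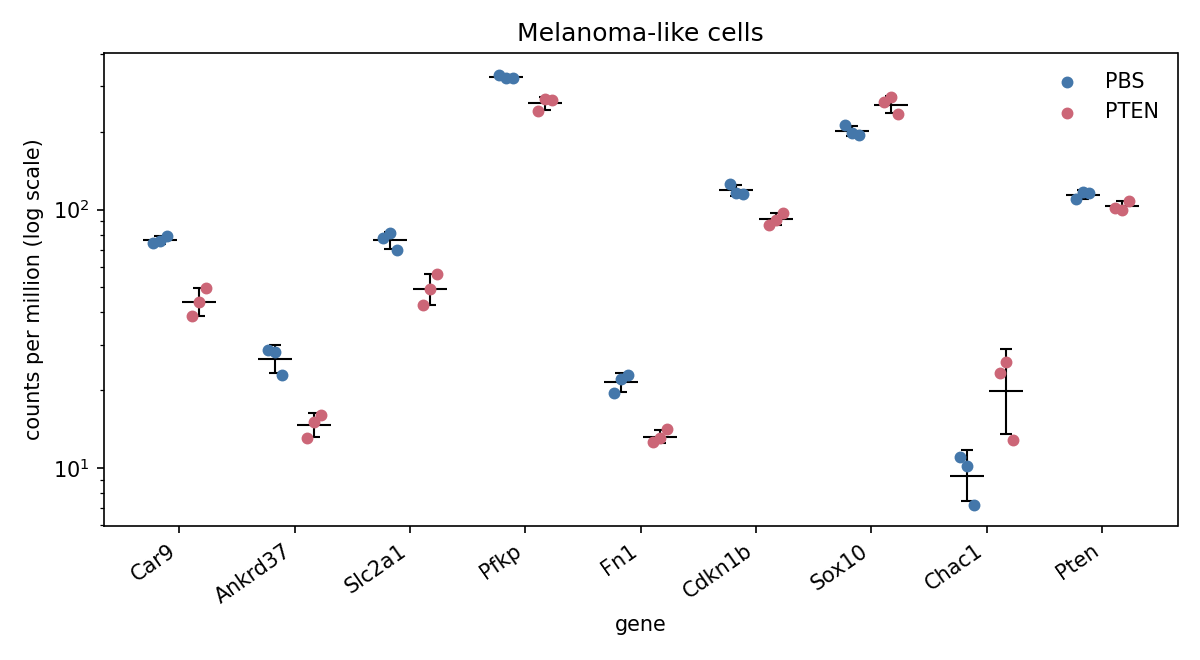
CPM of 9 named genes in melanoma-like cells, on a log axis, for each library (points, PBS in blue and PTEN in red); black bars mark the geometric mean and its SD on the log scale, n = 3 per group. Car9 lay between 74.2 and 79.2 CPM with PBS and between 38.8 and 49.7 CPM with PTEN.

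T cell-like cells had more transcripts of the granzymes Gzma and Gzmc with PTEN and fewer of the inhibitory receptor Lag3. The class pooled subclusters of differing mix. The subcluster led by Gzma held 5, 9 and 21 cells with PBS and 17, 19 and 20 with PTEN. The subcluster led by Tnfrsf4 and Icos, with Ikzf2 and Ctla4 among its leading genes, held 15, 21 and 7 with PBS and 9, 5 and 4 with PTEN. Both overlapped between the groups. A shift between subclusters and a change within cells are not separated by the sums. Gzma rose from 89.4 ± 63.1 to 1228 ± 847 CPM (SD, n = 3 each), by 3.65 ± 0.53 on the log2 scale (SE; edgeR adjusted p = 0.00508), and in the PTEN libraries stood at 16% of its level in NK cell-like cells. Gzmc rose by 4.07 ± 0.74 (SE; edgeR adjusted p = 0.0370) with overlapping libraries, at 7.02% of its own level in those NK cell-like cells, which leaves free RNA open. Lag3 fell by 1.29 ± 0.23 and the transcription factor Hivep1 by 1.32 ± 0.26 (SE; edgeR adjusted p = 0.0370 and 0.0455). Saa3 rose by 2.31 ± 0.44 (SE; edgeR adjusted p = 0.0418), at 0.549% of its level in monocyte/macrophage-like cells with PTEN. These were the 5 of 4837 genes that changed, 3 higher and 2 lower, with 579 at an unadjusted p under 0.05. Of 18 cytotoxic effector genes 2 rose and none fell (2 adjusted over the list alone), with a list median of -0.08, a mean of 0.35 and a test directed higher (adjusted p = 0.653). Of 12 exhaustion genes 1 fell and none rose (2 fell adjusted over the list alone). No gene passed among 10 naive or memory genes, 10 regulatory T cell genes, 23 interferon response genes, 13 FOXO targets or 26 cell cycle genes; adjusted over the list alone 2, 5, 0 and 2 fell in the first 4 and 9 cell cycle genes rose. Satb1 was at 0.25 ± 0.22, Ikzf2 at -0.71 ± 0.26, Ifi27l2a at 0.04 ± 0.26, Klf6 at -0.37 ± 0.17 and Top2a at 1.13 ± 0.31 (log2, SE, n = 3 per group). Camera at the preset correlation gave lower exhaustion (adjusted p = 9.36e-05) and regulatory T cell genes (1.73e-05) and higher cell cycle genes (1.44e-11), with adjusted p = 0.436, 0.480 and 0.480 with an estimated correlation. The naive or memory (adjusted p = 0.888), interferon (0.542) and FOXO (0.206) lists did not pass camera, FOXO targets with a median of 0.03, a mean of -0.11 and a test directed lower. Mitochondrially encoded RNA (median log2 0.38, adjusted p = 1.78e-07) and free melanoma RNA (0.39, 0.0194) were higher and stress genes lower (-0.29, 6.28e-05), with adjusted p = 0.480, 0.571 and 0.480 with an estimated correlation. DESeq2 called 47 genes, edgeR called 85 without a low-count filter, 15 with a stricter one and 17 with doublets kept, and limma with voom weights, the stricter cell filter and equal cell numbers each called 0. Gzma and Gzmc lost their calls in the last 3 and with doublets kept, and Lag3 and Hivep1 in the last 3 (adjusted p from 0.0589 to 0.308 over these 4 settings). The edgeR count was 1 without PBS replicate 1, 16 without PBS replicate 2, and 9, 2 and 11 without PTEN replicates 1, 2 and 3. Lag3 lost its call without PBS replicate 1 and PTEN replicates 1 and 2 (adjusted p from 0.0884 to 0.235), and Gzmc without PBS replicates 1 and 3 and PTEN replicates 1 and 2 (0.0521 to 0.144). Hivep1 lost its call without each library but PBS replicate 2 (0.0649 to 0.237), and Saa3 without each but PBS replicate 2 and PTEN replicate 1 (0.0855 to 0.140). Gzma kept its call under every left-out library.

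NK cell-like and conventional dendritic cell-like cells numbered under 20 in some library and were not tested. In NK cell-like cells the granzyme Gzmf had 33.5, 0 and 0 CPM in the PBS libraries and 7005, 18440 and 177 CPM in the PTEN libraries, and Gzma 5549 ± 1118 and 6584 ± 2798 CPM (SD, n = 3 each). Gzmf rested on 1 count with PBS. Cytotoxic effector genes went both ways, with Gzmc at 1625 ± 2373 and 6996 ± 1753 CPM (PBS and PTEN, SD, n = 3 each). Nkg7 stood at 1791 ± 302 and 1663 ± 170 CPM and Ccl3 at 343 ± 73.5 and 75.3 ± 25.8 CPM. Dendritic cell-like cells had 235 ± 75.9 and 12.6 ± 21.9 CPM of the chemokine Ccl22 and 124.7 ± 62.4 and 32.1 ± 5.04 CPM of Plxdc2, with 5331 ± 350 and 6165 ± 295 CPM of H2-Eb1 (PBS and PTEN, SD, n = 3 each).

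Neutrophil-like cells of the PTEN libraries had more Csf3 (log2 6.80 ± 0.42, SE; edgeR adjusted p = 8.88e-13), Saa3 (6.32 ± 0.34) and the transcriptional inhibitor Id3 (5.26 ± 0.39), and less of the proton pump subunit Atp6v0d2 (-4.79 ± 0.36), Cd200r4 (2 counts with PTEN, 25.3-fold lower, interval 6.62 to 215.6) and the neutrophil-attracting chemokine Cxcl3 (-2.95 ± 0.33). NF-kB feedback genes rose in 7 of 18 cases and fell in 2 (9 and 2 adjusted over the list alone), Sod2 at 1.78 ± 0.26 and Nfkb1 at 1.71 ± 0.26 (SE). Interferon response genes fell in 13 of 30 cases with none rising (16 adjusted over the list alone), Gbp2 at -1.25 ± 0.25 and Stat2 at -1.63 ± 0.34 (SE). Of 23 neutrophil activation genes 3 rose and 6 fell (3 and 8 adjusted over the list alone), and of 11 chemokines 1 rose and 3 fell (1 and 3 adjusted over the list alone). Camera at the preset correlation passed interferon response (adjusted p = 0.00272) and NF-kB feedback (0.00489), both at adjusted p = 0.565 with an estimated correlation, and not neutrophil activation (0.151) or chemokines (0.0677). Mitochondrially encoded RNA was higher, with 8 of 13 transcripts rising (median log2 0.69, adjusted p = 8.57e-06; adjusted p = 0.480 with an estimated correlation), while free melanoma RNA (0.41, 0.294) and stress genes (-0.15, 0.519) did not pass. In all, 1377 of 6018 genes changed, 551 higher and 826 lower. The PBS cells lay mostly in a cluster led by S100a9, S100a8 and Retnlg and the PTEN cells in a cluster led by Lcn2, Wfdc21 and Ccl3. Here too the sums do not separate replacement of cells from a change within cells. DESeq2 called 643, equal cell numbers 262, and leaving out PBS replicate 2, which held 954 of the 1154 PBS cells, gave 575, against 769 without PTEN replicate 2. Stat2 lost its call without PBS replicate 2 (adjusted p = 0.199) and by DESeq2.

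Endothelial cell-like cells of the PTEN libraries had fewer transcripts of Pgf and Ptn, of 15 of 31 interferon response genes and of 6 of 23 hypoxia response genes. Pgf, placental growth factor, fell by 3.47 ± 0.26 and Ptn, pleiotrophin, by 3.96 ± 0.70 on the log2 scale (SE; edgeR adjusted p = 3.11e-06 and 0.00368). The chemokine Ccl6 fell by 2.91 ± 0.54 (SE; edgeR adjusted p = 0.00512), but in the PBS libraries it stood at 1.34% of its level in monocyte/macrophage-like cells, which leaves free RNA open. Endothelial activation and tip cell genes fell in 9 of 16 cases with none rising (9 fell and 1 rose adjusted over the list alone), the Tie2 ligand Angpt2 at -1.46 ± 0.20 and Esm1 at -1.11 ± 0.16 (SE). Interferon response genes fell in 15 of 31 cases with none rising (24 adjusted over the list alone), the antiviral Rsad2 at -1.78 ± 0.25 and the immunity-related GTPase Iigp1 at -1.80 ± 0.26 (SE). Hypoxia response fell in 6 of 23 genes and rose in 1 (13 and 1 adjusted over the list alone), with the vasodilator adrenomedullin Adm at -2.07 ± 0.20 and Ndrg1 at -1.40 ± 0.18 (SE). In MHC class I presentation 1 of 17 genes fell and none rose (1 adjusted over the list alone; camera adjusted p = 0.150). Camera at the preset correlation passed tip cell genes (adjusted p = 1.21e-06), interferon response (1.76e-12) and hypoxia response (1.73e-05), each at adjusted p = 0.480 with an estimated correlation. Free melanoma RNA was higher (median log2 0.58, adjusted p = 0.00786; adjusted p = 0.565 with an estimated correlation), while mitochondrially encoded RNA (-0.02, 0.793) and stress genes (-0.02, 0.983) did not pass. Malat1, Gm42418, Lars2, Camk1d, Cmss1 and Gphn were lower with PTEN as well (median log2 -1.27), which leaves damage in the PBS cells open. This set was none of the tested lists and each member passed edgeR (adjusted p at most 0.00171), so its median describes these 6 transcripts alone. Lcn2 (1 count with PBS, 105-fold higher, interval 18.6 to 4177), Saa3 (log2 3.83 ± 0.57, SE) and S100a9 (2.67 ± 0.62, SE) rose while standing at 0.587%, 0.472% and 0.279% of their level in neutrophil-like or monocyte/macrophage-like cells of the PTEN libraries. In all, 915 of 8466 genes changed, 454 higher and 461 lower, in 44 to 60 cells per library. The count was 393 without PBS replicate 1, 276 without PBS replicate 2, 473 without PTEN replicate 1, 253 without PTEN replicate 2, 437 with doublets kept and 572 among cells of at least 5000 UMIs. S100a9 lost its call without PBS replicate 1 (adjusted p = 0.0509) and among the cells of at least 5000 UMIs (0.182).

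Fibroblast-like cells had 8 changed genes of 10397 by edgeR, 5 higher and 3 lower, with 1208 at an unadjusted p under 0.05. The carbonic anhydrase Car4 fell by 3.47 ± 0.38, the interleukin 13 decoy receptor Il13ra2 by 2.29 ± 0.31 and the phospholipase Plce1 by 1.40 ± 0.20 on the log2 scale (SE; edgeR adjusted p = 0.0154, 0.0247 and 0.0265). Cpz, a carboxypeptidase, rose by 1.51 ± 0.22 (SE; edgeR adjusted p = 0.0358), Lcn2 by 4.76 ± 0.61 at 2.15% of its level in neutrophil-like cells with PTEN, and Wfdc21, with 3 counts with PBS, was 44.2-fold higher (interval 14.5 to 219.5) at 0.567% of its own level there. No gene of the matrix and activated fibroblast list (29 measured), interferon response (35), MHC class I presentation (20) or chemokines (15) passed, and camera passed none (adjusted p = 0.173, 0.983, 0.130 and 0.983). Adjusted over the list alone 3 matrix genes rose and 1 fell, and 2 chemokines rose and 1 fell. Stress genes (median log2 0.36, adjusted p = 8.99e-09), mitochondrially encoded RNA (0.39, 1.29e-07) and free melanoma RNA (0.59, 5.71e-05) were higher by camera, each at adjusted p = 0.480 with an estimated correlation. DESeq2 called 92, and edgeR called 486 without a low-count filter, 24 with a stricter one, 3 with doublets kept and 21 with equal cell numbers. The count was 4, 3 and 2 without PBS replicates 1, 2 and 3, and 16, 3 and 0 without PTEN replicates 1, 2 and 3. Leaving out PTEN replicate 3 ended the calls of all 6 named genes (adjusted p from 0.0636 to 0.0868), PBS replicates 1 and 3 those of 5 each, PBS replicate 2 and PTEN replicate 2 those of 4 each, and PTEN replicate 1 that of Cpz (0.0531). Keeping doublets ended the calls of Car4, Cpz and Plce1 (adjusted p from 0.0503 to 0.0832), voom weights those of Lcn2 and Il13ra2 (0.0563 and 0.0804), and equal cell numbers that of Il13ra2 (0.0609).

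Sums over all kept cells, free of cluster names, gave 142 changed genes of 18982, 17 higher and 125 lower with PTEN. Saa3 rose by 4.00 ± 0.36 on the log2 scale (SE; edgeR adjusted p = 0.0132). Fam178b, Npnt, Ramp2, Gcat and Gamt rose by 0.64 ± 0.10, 0.60 ± 0.09, 0.51 ± 0.06, 0.50 ± 0.07 and 0.49 ± 0.07 (SE). Retnla was at least 670-fold and the lectin Cd209a at least 87.3-fold lower, and Ccl24 and Ccl22 changed by -8.31 ± 0.85 and -6.29 ± 0.78 (SE). Mgl2, with 2 counts with PTEN, was 855-fold (interval 236 to 7068) and Cd209d, with 1, 153-fold (interval 27.0 to 6072) lower. Plxdc2 stood at 19.5 ± 2.67 and 15.8 ± 1.66 CPM and Plxdc1 at 5.62 ± 0.537 and 6.14 ± 0.958 CPM (SD, n = 3 each; edgeR adjusted p = 0.197 and 0.629). Markers of dendritic cells fell in 6 of 12 cases and of B cells in 2 of 8, with none rising (7 and 6 fell adjusted over the list alone). Of the other lists called below, 1 of 10 monocyte markers, 1 of 12 macrophage markers and 1 of 38 interferon response genes fell. No gene passed edgeR among 10 fibroblast, 9 pericyte, 8 plasmacytoid dendritic cell, 10 melanoma and 9 NK cell markers. Adjusted over the list alone, 5 monocyte, 1 macrophage, 4 interferon response, 9 fibroblast and 3 plasmacytoid genes fell and 3 melanoma and 1 NK cell marker rose. By camera at the preset correlation, dendritic cell (adjusted p = 8.99e-09), B cell (6.68e-05), fibroblast (1.50e-05), monocyte (0.00267), plasmacytoid dendritic cell (0.00614), pericyte (0.0119) and macrophage markers (0.0470) and the interferon response (1.34e-08) were lower, and melanoma (0.00318) and NK cell markers (0.0143) higher. With an estimated correlation the adjusted p was 0.436 for dendritic cell markers, 0.480 for B cell, fibroblast and plasmacytoid markers, 0.522 for pericyte, 0.581 for monocyte, 0.709 for macrophage, 0.524 for interferon response and 0.565 for melanoma and NK cell markers. Markers of neutrophils (adjusted p = 0.651), T cells (0.390), endothelial cells (0.542), red blood cells (0.449) and Schwann cells (0.409) did not pass. The neutrophil and red cell lists had medians of -0.42 and -0.33 with tests directed higher, and the Schwann list a median of 0.13 and a mean of -0.08. Mitochondrially encoded RNA (median log2 0.22, camera adjusted p = 0.00118) and the free melanoma RNA list (0.19, 0.0242) were higher, both at adjusted p = 0.565 with an estimated correlation, and stress genes did not pass (-0.27, 0.160). In whole libraries the free melanoma RNA list includes the melanoma-like cells' own transcripts, so it does not measure free RNA. DESeq2 called 1870 genes. The edgeR count was 86 and 13 without PBS replicates 2 and 3, and 2, 8 and 817 without PTEN replicates 1, 2 and 3. Leaving out PTEN replicate 1 ended the calls of 11 of the 12 named genes (adjusted p from 0.0666 to 0.187), Retnla apart. Leaving out PTEN replicate 2 ended 10, PBS replicate 3 ended 9, PBS replicate 2 ended 5 and PBS replicate 1 ended 4 of these calls, the rises of Fam178b, Gcat, Gamt and Ramp2 in each case. Voom weights ended the calls of Fam178b and Ccl24 (adjusted p = 0.0542 and 0.133), equal cell numbers that of Fam178b (0.0553), and doublets kept and the stricter cell filter that of Npnt (0.0614 and 0.0506).

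Of the 76 tests of a gene list in a class, 44 passed camera at the preset correlation and 0 passed with an estimated correlation. The directional test of fry passed 3: alternatively activated macrophage genes and phagocytosis receptors in monocyte/macrophage-like cells (adjusted p = 0.0196 for both) and dendritic cell markers in whole libraries (adjusted p = 0.000512). The mixed test of fry, which asks for change in either direction, passed more. It passed MHC class II and NF-kB feedback in monocyte/macrophage-like cells (adjusted p = 0.0099 for both) and hypoxia response in melanoma-like cells (0.012). It did not pass interferon response in melanoma-like cells (adjusted p = 0.251) or the cell cycle in T cell-like cells (0.0636). An exchange of libraries between the groups, with PBS replicates 1 and 2 and PTEN replicate 3 set against the rest, gave 47 lists at the preset correlation, more than the real groups.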

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

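Of the tests below, the exchanges of libraries for counts of genes, the share of free RNA in monocyte/macrophage-like cells, the levels within the same group and the reading of interferon genes for a microbial component were chosen only after the results were seen. Macrophage-like clusters alone were an alternative of the original plan, but the percent of genes asked of them was set after the results were seen. Barcodes above 20% mitochondrial UMIs, left out of every comparison, made up 9.976% of barcodes on average in the PTEN libraries and 6.17% in the PBS libraries, with all 3 PTEN libraries above all 3 PBS libraries (exact permutation p = 0.1, the smallest possible). Melanoma markers held 1.81% and 1.65% of their other UMIs.

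The 6 libraries can be parted in 10 ways, which are too few for a share under 0.05. As many changed genes as with the real groups came from 1 of the 10, the real one, in each class. The real groups gave 1079 genes in monocyte/macrophage-like cells (highest other 0), 365 in melanoma-like cells (0), 5 in T cell-like cells (0), 1377 in neutrophil-like cells (4), 915 in endothelial cell-like cells (3), 8 in fibroblast-like cells (1) and 142 in whole libraries (2). For gene lists 2 of the 10 gave as many, the real groups with 44 and PBS replicates 1 and 2 with PTEN replicate 3 with 47, and no list passed with an estimated correlation.

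Monocyte/macrophage-like cells of the PTEN libraries had more Saa3, Marco and Fpr1 and less Retnla, Ccl24 and Mrc1, and 7 of 9 MHC class II genes fell (camera adjusted p = 0.480 with an estimated correlation). Monocyte-like cells at the finer resolution were 21.8%, 11.7% and 20.0% of the class with PBS and 3.16%, 0.777% and 3.43% with PTEN. They cannot be the only source of most calls, since 84.62% of the changed genes were also called in macrophage-like clusters alone. Those clusters themselves parted by group at resolution 1. The cluster led by Arg1 held 497, 1353 and 829 cells with PBS and 21, 18 and 45 with PTEN. The cluster led by Saa3 held 45, 60 and 41 with PBS and 483, 534 and 664 with PTEN. Replacement of macrophage-like cells by others and a change of transcripts within cells are therefore not separated. Of the changed genes, 4.078% lay under 10% of their CPM in another class pooled over both groups. In the same group 5.28% did. These low shares cannot decide on free RNA. In PTEN replicate 1 melanoma markers held 0.277% of UMIs in monocyte/macrophage-like and 2.11% in melanoma-like cells, so free melanoma RNA can stand above 10%. Saa3, Marco, Ccl24 and Mrc1 stood at 608%, 16300%, 353% and 358% of the highest other class in the same group, which argues against free RNA for them. Free RNA stays open, at least in part, for Lcn2, Csf3, Fpr1, Mgl2 and Plxdc2 (2.70%, 7.47%, 9.46%, 6.76% and 7.31% in the same group). A microbial component carried with the injected PTEN cannot be told apart from PTEN itself: the interferon response list had a median log2 change of -0.5062 while 8 NF-kB feedback genes rose, and no inactive protein was injected for comparison. A direct response of macrophages to PTEN is therefore only 1 candidate explanation.

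Myeloid transcripts such as Saa3, Lcn2, Retnla and Ccl24 differed between the groups in melanoma-like cells. Of the 365 changed genes 98 lay under 10% of their CPM in another class pooled over both groups, and of 97 tested 91.75% had the sign of their change in the sum of all other cells. Set against another class in the same group, 101 lay under 10%, and 92 of 100 tested had that sign. Free RNA or remaining doublets may account for them. A change shared by all cell classes would give the same signs, so the signs cannot separate it from free RNA or doublets. Fn1, at 0.967% of its level in fibroblast-like cells with PBS, is among the 101 genes, while 264 changed genes, with Car9, Ankrd37 and Slc2a1 among them, are not.

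Endothelial cell-like cells of the PTEN libraries had less Pgf, Angpt2, Adm and Rsad2. Shallower or damaged cells in the PBS libraries could add to this. Among cells of at least 5000 UMIs 100% of 908 tested genes had at least 0.5 of their log2 change, yet those cells held 95.0% of the class's UMIs, so the sums hardly differed and this test could not have shown depth or damage. The transcripts Malat1, Gm42418, Lars2, Camk1d, Cmss1 and Gphn were lower with PTEN (median log2 -1.27, and -1.29 in the deep cells), which leaves damage in the PBS cells open. All but Malat1 also led unnamed shallow clusters. The set was none of the tested lists and leaves out other leading genes of those clusters, such as Gm26917 and Cdk8, so its median is no measure of damage. For the changed genes of this class an effect of PTEN and a difference in cell quality cannot be told apart.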

How the results depend on the processing

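Endothelial cell-like cells of at least 5000 UMIs were the only setting of this paragraph chosen after the data were seen; the cause of each move was not tested. The count of changed genes in melanoma-like cells, 365 by edgeR, was 1316 by DESeq2 and 588 without a low-count filter, and ranged from 35 (without PTEN replicate 2) to 952 (without PTEN replicate 3) over left-out libraries. In monocyte/macrophage-like cells that range was 624 (without PTEN replicate 2) to 1151 (without PBS replicate 2). T cell-like cells gave 47 by DESeq2, 85 without a filter, 15 with a strict filter and 17 with doublets kept. They gave 0 with the stricter cell filter, 0 with equal cell numbers, 0 by limma with voom weights, and 1 and 16 without PBS replicates 1 and 2. Neutrophil-like cells gave 643 by DESeq2 and 262 with equal cell numbers, and 575 to 1658 without PBS replicates 2 and 1. Endothelial cell-like cells gave 437 with doublets kept, 572 among deep cells, and 253 to 933 without PTEN replicates 2 and 3. Fibroblast-like cells gave 92 by DESeq2, 486 without a filter, 24 with a strict filter, 3 with doublets kept, 21 with equal cell numbers, and 0 and 16 without PTEN replicates 3 and 1. Whole libraries gave 1870 by DESeq2, and 2 and 817 without PTEN replicates 1 and 3. With the replicate number as a block, endothelial cell-like cells gave 274, fibroblast-like cells 141 and whole libraries 26, and no pairing of libraries is stated. That block also ended the calls of Lag3 and Hivep1 in T cell-like cells (adjusted p = 0.0528 and 0.0577), Ccng2 in melanoma-like cells (0.0565), S100a9 in endothelial cell-like cells (0.0594) and 9 of 12 named genes in whole libraries, Saa3, Cd209a, Cd209d and Ccl22 among them (0.0560 to 0.106). Of 76 tests of gene lists, 44 passed at the preset correlation, 0 with an estimated correlation and 3 by directional fry, 2 of them among the 44. The list of MHC class I presentation in melanoma-like cells, uncalled with all libraries, had a median of -0.3344 without PBS replicate 1. Without PBS replicate 3 it turned to 0.1003 and passed camera as higher (adjusted p = 0.0236). Interferon response in fibroblast-like cells, also uncalled with all libraries, went from -0.1586 to 0.1339 in the same way (camera adjusted p = 0.0191 without PBS replicate 3). Among cells outside the melanoma-like class, log2 ratios of shares were -0.2316 for monocyte/macrophage-like, 0.4999 for T cell-like, 1.195 for NK cell-like, 0.19 for endothelial cell-like and -0.3546 for pericyte or smooth muscle-like cells, and 1.222 for neutrophil-like, -0.4521 for fibroblast-like and 0.6349 for red blood cell-like cells. Dendritic cell-like cells had -2.644 by edgeR on counts and -3.276 at resolution 2. Neutrophil-like shares had -0.01091 and 2.384 without PBS replicates 1 and 2, and red blood cell-like shares -0.7491 and 1.857 without PTEN replicate 3 and PBS replicate 2. Pten stayed uncalled under every left-out library in monocyte/macrophage-like, melanoma-like and T cell-like cells and in whole libraries.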

Other observations

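Csf3, the granulocyte growth factor, was among the genes of largest rise in both myeloid classes with PTEN, at 21.6 ± 10.6 CPM in monocyte/macrophage-like and 285 ± 58.1 CPM in neutrophil-like cells (SD, n = 3 each), against 0.885 ± 1.13 and 0.960 ± 1.66 CPM with PBS. The highest level therefore lay in the neutrophil-like cells, and the 7.47% of it found in monocyte/macrophage-like cells with PTEN leaves free RNA open there. Saa3 rose in both classes and stood highest in monocyte/macrophage-like cells, with neutrophil-like cells at 13.8% of that level with PTEN. Of the interferon response genes, 14 fell, 1 rose and 23 did not pass in monocyte/macrophage-like cells, and 13 fell and 17 did not pass in neutrophil-like cells, with list tests at adjusted p = 0.498 and 0.565 with an estimated correlation. Sod2, an NF-kB feedback gene, rose by 1.79 ± 0.16 and 1.78 ± 0.26 on the log2 scale (SE, n = 3 per group).

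B cell-like cells, led by antibody genes such as Igkc, Ighg2b and Jchain, numbered 90, 82 and 46 with PBS and 22, 2 and 18 with PTEN. Their median depth was 1678.5, 2069 and 1563.5 UMIs per cell with PBS and 7192, 2342 and 8004.5 UMIs with PTEN, so that the fewer B cell-like cells of PTEN replicates 1 and 3 held more RNA each. Ankrd37, a hypoxia response gene, fell in both melanoma-like and monocyte/macrophage-like cells. In the latter its call was lost without PBS replicate 3, PTEN replicate 1 or PTEN replicate 2. Of that list 2 of 23 genes fell and 21 did not pass in monocyte/macrophage-like cells. In endothelial cell-like cells, where damage in the PBS cells stays open, 6 of 23 fell, 1 rose and 16 did not pass.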
